A study of Danio rerio with 11 samples.

How the data were processed

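The series holds 11 samples of zebrafish tissue from 5 multiome preparations, each giving RNA and open chromatin from the same nuclei, and 1 separate chromatin preparation of EF1 nuclei at 7 dpf. Per the labels' protocols, control fish at 7 dpf carried Sox10:Cre and a color switch reporter that turns on DsRed, EF1 fish also carried a switch that turns on GFP and human EWSR1::FLI1, trunks were cut behind the ear without the swim bladder, and cells were sorted for DsRed (control) or GFP (EF1). Adult tissues were not sorted: a trunk tumor and wild-type control trunk tissue at 3 mpf and a head tumor of a mosaic model at 9 mpf. Per the labels, the separate EF1 chromatin library is of another strain mix than the other samples. The groups were taken from the labels; each RNA group had 1 library and the EF1 chromatin group 2.

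The deposited matrices hold raw counts, UMI counts per gene and nucleus and transposition cut site counts per peak and nucleus, in nuclei that Cell Ranger had kept, per the labels' protocols with alignment to GRCz11. Which Cell Ranger version made which matrix is not stated for the multiome files. Per the submitters' processing notes, their own later steps used R 4.1.3, Seurat 4.3.0 and Signac 1.6.0; nothing made by those steps was deposited or used here. The 7 dpf files list 31822 gene symbols and the adult files 26908, so joint clustering and gene sets read across ages used only symbols in both. CPM was scaled to each library's own total, so levels at 7 dpf and in adults are not directly comparable. The 7 dpf annotation has rows for EGFP, DSRED and the fusion, and the adult one has 1 transgene row.

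Nuclei were kept with at least 500 UMIs, no doublet call and under 10% of UMIs in mitochondrial rows named mt-, which leave out mitochondrial ribosomal RNA. This kept 242 of 370 EF1 nuclei (612475 UMIs, median 1866.5), 1365 of 1854 control nuclei at 7 dpf (1938505, median 987), 1962 of 2884 trunk tumor nuclei (4025289, median 1743.5), 3125 of 3399 head tumor nuclei (7474522, median 2176) and 2550 of 3562 adult control nuclei (6648013, median 2267). The doublet caller, scrublet within scanpy 1.11.5, marked 25 of 10144 scored nuclei (0.246%), far below the share such loading gives, so it did not work here and doublets remain. UMIs were summed per library and scaled to CPM, with Python 3.11, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

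Ratios between libraries carry an exact conditional binomial 95% interval for a pair of Poisson counts, and shares an exact Clopper-Pearson interval. A gene with 0 UMIs in a library was set to a floor of 3 counts for that library, which makes its fold a lower bound; such genes enter list medians at that bound. No test between groups was run. The 24 gene lists, the naming rule, the filters and the comparisons were fixed before the data were examined, except where the text says otherwise. A list's members count as measured with at least 20 UMIs summed over both libraries, and a list's median was placed among the medians of 10000 random lists matched on expression. The shift of all genes was taken by median of ratios scaling. List medians carry intervals from redrawn Poisson counts.

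Named genes are the 12 highest and 12 lowest by the end of the interval nearest to 1, among genes with at least 50 UMIs and 10 CPM in a library, leaving out mitochondrial, ribosomal protein, haemoglobin and unnamed genes. Up to 4 members per list with the largest ratios were added, together with the transgene rows, fli1a, fli1b, ewsr1a, ewsr1b and sox10. For 1 gene, which still counts in its list, the single-gene result is not reported here. The acinar list of 24 genes was written after acinar transcripts were seen at 7 dpf. Genes followed across clusters (tbxta, lepb, pdgfra, crestin, the transgene and others) and the pairs of clusters compared were also chosen after their values were seen.

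Kept nuclei of the 5 libraries were clustered together without batch integration: log normalization, 3000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0), leaving out mitochondrial, ribosomal protein and transgene rows. A cluster was named after a cell type when at least 3 of that type's listed markers were 2-fold above the other clusters and found in at least 5% of nuclei, that number was more than 2 times that of the next type, and a marker stood among the 50 leading genes. Among the 10 genes with the highest fold, no other type could have more markers, and fewer than 3 could be acinar. A cluster far shallower than its main library, with no marker of its type among these 10 genes, was not named. The acinar condition used the list written after the data were seen. This rule was tightened after its first version, which needed a lead of 2 markers, was seen: the first version called cluster 5 fibroblast-like (36.7% of trunk tumor, 1.31% of head tumor and 0 adult control nuclei), cluster 12 macrophage-like (5.30%, 4.54% and 3.02%) and cluster 13 skeletal muscle-like (99.2% of EF1 nuclei at 7 dpf), and these stay unnamed here. Which of the conditions removed each name was not separated.

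Peaks were compared by overlap of at least 1 bp; EF1-only peaks are peaks of the EF1 multiome library that overlap a peak of the separate EF1 library and none of the control. The peak lists hold 127356 peaks for the trunk tumor, 139350 for the head tumor, 107527 for the adult control and 146688 for the separate EF1 library. Genome sequence was not used here, so the planned search for GGAA repeats, the consensus motifs in peaks and the genes near repeat peaks were not run.

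The steps were tested on simulated data, Poisson counts drawn around each comparison's pooled levels, with 200 genes given a known fold. For true 2-fold genes the direction was right in 98.4% (7 dpf), 100% (trunk), 96.8% (head) and 100% (trunk against head), and in 100% of 4-fold and 8-fold genes in each comparison. A true 2-fold change was called by size in 56.5%, 39.7%, 45.2% and 58.3% of genes, and unchanged genes in 7.20%, 2.50%, 1.73% and 2.58%. The 95% interval held the truth for 96.0%, 96.1%, 96.0% and 95.9% of unchanged genes. For changed genes the share ran from 91.8% (head, 4-fold) to 100% (7 dpf, 4-fold). The simulated counts follow the model that the interval assumes, without spread between nuclei, free RNA or a shift of all genes. Its coverage therefore checks the calculation and not the fit of that model to these data. Of 200 unchanged lists of 15 genes, 11, 7, 13 and 12 fell outside the central 95% of random lists, and a list of 2-fold genes stood at the percentile of 100 in each comparison. The simulated unchanged genes varied by counting only, so this does not show that such a list stands out in the real data. There the trunk cell cycle median of 1.40 stood at the percentile of 94.0, within the central 95% of random lists (-0.02 to 1.57).

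The settings chosen before the data were seen were median of ratios scaling, at least 1000 UMIs per nucleus, called doublets kept, all deposited nuclei, list members with at least 5 UMIs, nuclei thinned to 500 UMIs, Leiden resolutions of 0.5 and 2, derived sets of 25 and 100 genes, overlap of at least 50% of the smaller peak, and the 20000 peaks with the most cut sites. Chosen after seeing the data were removal of the nuclei with the highest doublet scores, leaving out mitochondrial transcripts, control without epidermis-like clusters, derived sets without acinar and muscle genes, and leaving out each EF1 chromatin library. Figures were drawn with matplotlib 3.10.9.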

Results

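The libraries address what the fusion oncogene EWSR1::FLI1 (EF1) does to zebrafish cells of the Sox10 lineage, which includes the neural crest, and what the resulting tumors express. Nuclei sorted at 7 days post fertilization (dpf) from trunks with EF1 were compared with sorted control nuclei, and unsorted nuclei from a trunk tumor at 3 months post fertilization (mpf) and a head tumor at 9 mpf were compared with wild-type control trunk tissue at 3 mpf. Each RNA group held 1 library, so no test between groups was possible, and the intervals given are exact 95% intervals that cover counting error only. A gene is called higher or lower by size when its CPM ratio was at least 2-fold, where CPM is a gene's UMIs scaled to the library's total. Values for gene lists are median log2 ratios, given as measured and then relative to the shift of all genes.

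At 7 dpf the EF1 nuclei had far fewer transcripts of neural crest derivatives than the control nuclei. The regulator of neural crest and glia sox10 had 9 UMIs against 364, which is 12.8-fold lower (6.66 to 28.2), and foxd3, another neural crest transcription factor, had 0 against 137, at least 14.4-fold lower. The myelin basic protein gene mbpa was 123-fold lower (52.6 to 379). In the other direction tbxta, the Brachyury gene of early mesoderm and notochord, had 39 UMIs in EF1 nuclei against 4 in control nuclei, a 30.9-fold higher level (11.1 to 119), and pdgfra, a growth factor receptor of mesenchyme, was 12.2-fold higher (8.25 to 18.4). The highest ratios of all belonged to digestive enzymes of the exocrine pancreas, an organ outside the Sox10-lineage gate. With 0 UMIs in the transgene rows, the RNA did not show which of the sorted nuclei expressed EF1. The lower levels thus describe the sorted nuclei, and other nuclei in the sort were not separated from an effect of EF1.

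The median of all 8973 genes with at least 20 UMIs was a log2 ratio of -1.26, and median of ratios scaling placed the shift at -1.20. By size 597 genes were higher and 5336 lower, so 10.1% of them were higher; after scaling the numbers were 1847 and 2129, or 46.5%. Mitochondrial ribosomal RNA, a sign of cytoplasmic RNA among nuclei, made up 27.9% of the UMIs in the EF1 library and 17.7% in the control library. It was not part of the mitochondrial filter. Of the kept UMIs, 65.5% in the EF1 library and 77.2% in the control library lay outside all mitochondrial rows.

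Of the 8 measured neural crest genes, 6 were lower by size and 0 higher, with a list median of -3.11 (-1.92 relative to the shift). Among them pax3a had 1 UMI against 124 and ets1 had 1 against 45. Schwann cell and myelin genes were lower in 15 of 17 members, with a median of -3.70 (-2.50 relative to the shift), below every one of 10000 random lists matched on expression. Besides mbpa, the myelin genes mbpb, cldnk and plp1b were 56.5-fold, 43.0-fold and 61.6-fold lower. All 16 genes of peripheral neurons were lower, with a median of -4.23 (-3.03 relative to the shift), among them phox2bb and ret, which act in autonomic and enteric neurons, and the growth cone gene gap43. Pigment cell genes were lower in 9 of 13 members, with a median of -2.34 (-1.14 relative to the shift), including tyrp1b of melanin synthesis with 0 UMIs against 414, at least 43.6-fold lower, kita, pmela and slc45a2. The lowest ratios in the library outside these lists included vipb, which encodes a neuropeptide of gut neurons, at 8 UMIs against 4756, the sodium channel gene scn4ab at 4 against 2176, the neuronal nitric oxide synthase gene nos1 at 2 against 976, znf536, chl1b, ntm, zwi, nlgn3a and the GDNF receptor gene gfra1a.

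Early and posterior mesoderm genes were mostly near or below the count limit, with 3 of the 28 listed genes measured. Their median of 1.90 (0.38 to 3.04, and 3.10 relative to the shift) was the value of meox1, a homeobox gene of somites, with 13 UMIs against 11. The gene tbxta was also higher, while hoxb1b had 2 UMIs against 21. A tbxta UMI was found in 12.8% (8.87 to 17.7) of the 242 EF1 nuclei, at a median depth of 1866.5 UMIs, and in 0.220% of the 1365 control nuclei, at a median depth of 987. Muscle and acinar RNA was spread over the same EF1 nuclei, and 39 UMIs could not separate tbxta in few nuclei from an even spread. Fin and limb development genes had a median of -0.47 that turned to 0.72 relative to the shift, with the fin fold genes hmcn2 and and3 3.69-fold and 3.07-fold higher, sall4 2.92-fold higher and hand2 17.3-fold lower. Posterior hox genes were lower in 4 of 6 members, with a median of -1.33 (-0.14 relative to the shift), and hoxa9b had 2 UMIs against 30. Anterior hox genes were lower in all 12 members, with a median of -2.02 (-0.82 relative to the shift); hoxb5a and hoxb5b had 1 UMI each against 117 and 100.

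Fibroblast and extracellular matrix genes were higher by size in 12 of 23 members and lower in 0, with a median of 1.16 (2.36 relative to the shift). Examples are postnb (9.77-fold), col6a2 (6.65-fold) and dcn (5.38-fold). Orthologs of genes that human EWSR1::FLI1 represses had a median of 0.59 (1.78 relative to the shift), with 7 of 21 members higher and 7 lower by size; tagln and acta2, which encode contractile proteins of smooth muscle and myofibroblasts, were 14.5-fold and 6.10-fold higher. Orthologs of genes that it activates were lower in 17 of 25 members and higher in 3, with a median of -1.34 (-0.14 relative to the shift). Their lowest members, mapta, sox2, cd99l2 and egr2b, include neuronal and glial genes.

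Skeletal muscle, pancreas and skin transcripts were higher in the same EF1 library. All 14 muscle genes were higher, with a median of 6.85 (8.04 relative to the shift): mylpfa had 635 UMIs against 6, and actc1b had 1915 against 26. A list of acinar enzymes, written after these genes were seen, had 20 of 21 measured members higher and a median of 9.01 (10.2 relative to the shift). The trypsin-type protease genes prss59.2 (4375 UMIs against 0, at least 4616-fold), prss1 and prss59.1, the chymotrypsin genes ctrb1 and ctrl, and the elastase genes ela3l, ela2, ela2l and cela1.6 all belong to it, as do cpa5 and sycn.2; apoda.2 (662 against 1) does not. Epidermis genes were higher in 6 of 9 members, with a median of 2.65 (3.85 relative to the shift), such as krt4 at 14.9-fold and cldne at 63.8-fold. The epithelial ETS factor gene elf3 was 36.1-fold higher, while etv1 was 28.2-fold lower.

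Other lists were lower or near the shift. Cell cycle genes were lower in 13 of 14 members, with a median of -2.57 (-1.38 relative to the shift), among them top2a, aurkb and pcna (9.93-fold). Central nervous system genes were lower in all 9 members, with a median of -2.80 (-1.60 relative to the shift), such as nrxn1a at 3 UMIs against 389. Cartilage and bone genes were lower in 3 of 4 members, with a median of -2.27 (-1.08 relative to the shift). The medians of FGF-ERK feedback (-0.97), ETS factor (-1.16) and apoptosis and p53 genes (-0.16) turned positive relative to the shift, at 0.23, 0.04 and 1.03, as did that of dissociation and stress genes, from -0.03 to 1.17. Chromatin regulators had a median of -1.45 (-0.26 relative to the shift), and Hedgehog, BMP, Wnt and Notch response genes one of -1.30 (-0.11 relative to the shift). Of the immune genes lyz had 39 UMIs against 0 and cd79a 2 against 28, which gave a median of 1.61 (2.80 relative to the shift), and no endothelial gene was measured. The rows for EGFP, DSRED and the EF1 transgene had 0 UMIs in both 7 dpf libraries, although the cells had been sorted on GFP or DsRed. It is open whether these rows can count such RNA in that reference, so the 0 does not measure the transgene's level. Of the genes that make up the fusion's zebrafish counterparts, fli1a was 4.07-fold higher (1.35 to 12.9), fli1b had 0 UMIs in both libraries, ewsr1a had 0 against 48 and ewsr1b was 3.36-fold lower.

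**Figure D1:**
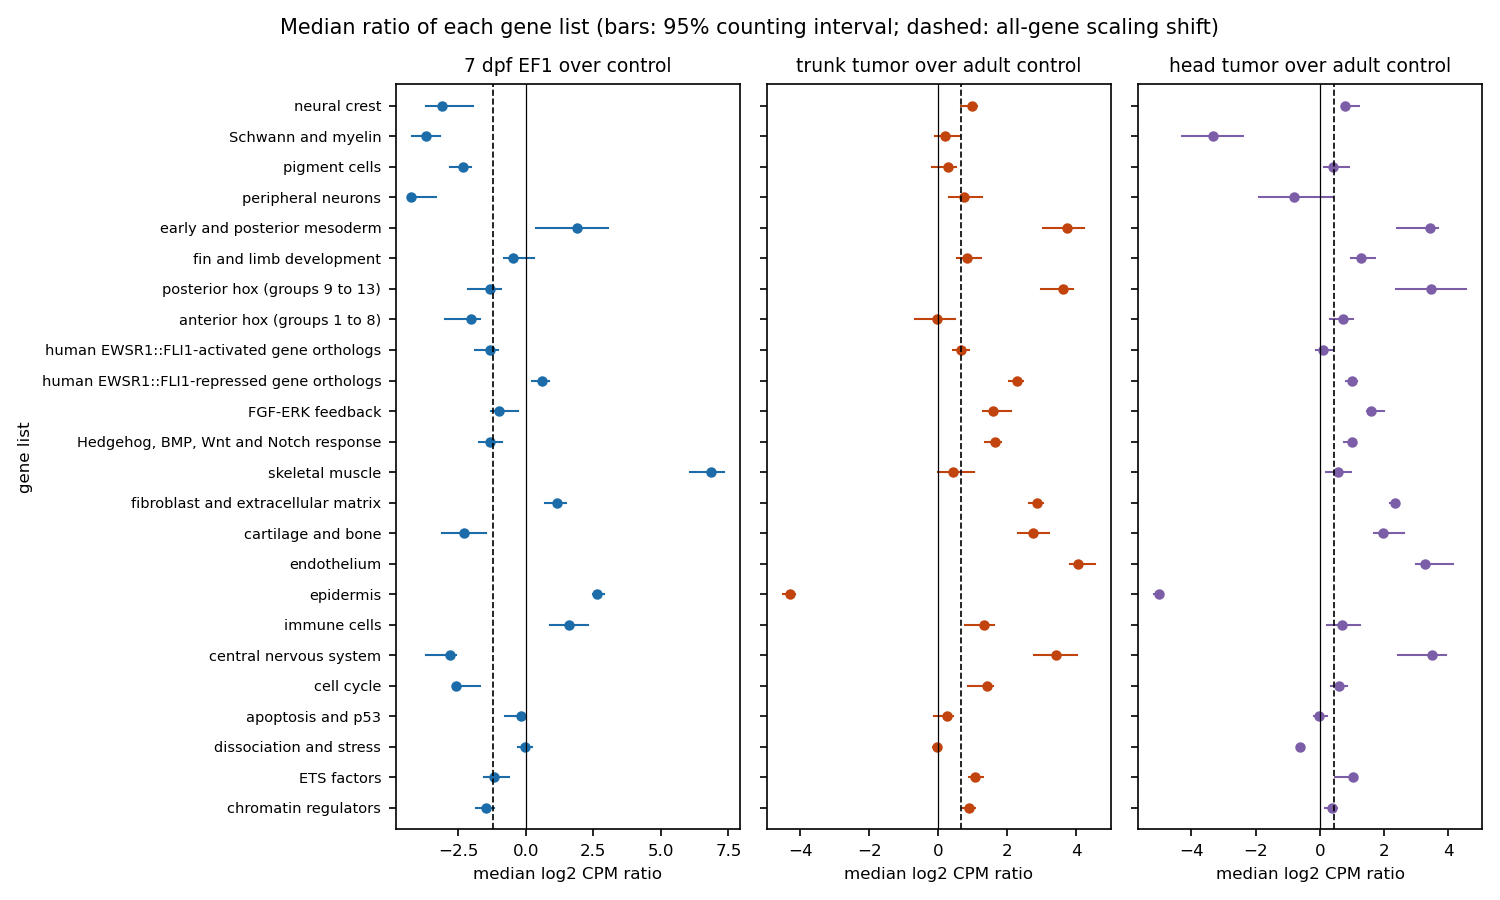
Median log2 CPM ratio for each gene list (rows) in the 7 dpf EF1 library over its control, the trunk tumor over adult control and the head tumor over adult control, with 95% counting intervals as bars and the shift of all genes dashed. Early and posterior mesoderm sits at 1.90, 3.72 and 3.42, to the right of the shift in each panel, over 3, 9 and 11 measured genes. Medians between the dashed line and 0, such as FGF-ERK feedback (-0.97) at 7 dpf and pigment cells in both tumors (0.28 and 0.42), change sign with the scaling.

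In the trunk tumor the mesoderm gene tbxta had 1044 UMIs against 0 in control tissue, at least 575-fold higher, and its paralog tbxtb, with 0 UMIs in control, was at least 57.8-fold higher. The EF1 transgene itself had 1389 UMIs against 0, at least 765-fold higher. The mesenchymal receptor gene pdgfra was 185-fold higher (136 to 258), with 4582 UMIs against 41. Keratinocyte genes went the other way, with the adhesion gene epcam 27.7-fold lower (26.0 to 29.6). Both libraries were unsorted, and 78.9% (77.3 to 80.5) of the control nuclei but 4.38% (3.52 to 5.39) of the tumor nuclei fell in epidermis-like clusters, so cell makeup enters each of these ratios.

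The shift of all 15842 genes was 0.65, with 6494 genes higher and 2464 lower by size (72.5% higher), and 4345 and 4098 after scaling (51.5%). The highest ratios belonged to stmn4, a neuronal stathmin, with 5938 UMIs against 2, the transgene, tbxta, vwc2l, the leptin gene lepb (1264 against 2), the synaptic scaffold gene homer1b, lrp1ba of the LDL receptor family (386-fold), shisa2b, the homeobox gene meox2b, the glycosyltransferase gene large2 (249-fold), nxph1 and the basement membrane gene nid1b (263-fold). The lowest were the mucin genes muc5.2 (114-fold lower) and muc5.1, cckb, the transglutaminase gene tgm5l (80.3-fold), malb, fabp1b.2, the sterol synthesis genes hsd17b7 and cyp51, cyp8b3, tmprss13b, agr1 and entpd8.

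Early and posterior mesoderm genes had a median of 3.72 (3.05 to 4.23; 3.08 relative to the shift), above all 10000 matched random lists, with 6 of 9 members higher and 1 lower. Besides tbxta and tbxtb, these were led by ripply1 of somite boundaries (119 UMIs against 1) and the mesendoderm gene mixl1 (57 against 2). Posterior hox genes were higher in 8 of 10 members and lower in 0, with a median of 3.62 (2.97 relative to the shift): hoxa11b was 30.1-fold higher, and hoxc11a and hoxb13a had 37 and 26 UMIs against 0. The 4 measured anterior hox genes had a median of -0.03 (-0.67 relative to the shift), with hoxa4a 3.12-fold lower. Fin and limb genes were split, with 10 of 20 higher, 5 lower and a median of 0.82 (0.18 relative to the shift); sall1a was 20.9-fold higher, and msx2b and sp8a were 33.4-fold and 20.9-fold lower.

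All 29 measured fibroblast and matrix genes were higher by size, and 25 remained so after scaling, with a median of 2.86 (2.63 to 3.03; 2.21 relative to the shift). They include mfap2 (49.2-fold), prrx1b (38.5-fold) and pdgfrb (28.2-fold). Against the control nuclei outside the epidermis-like clusters, a comparison chosen after the data were seen, the matrix median was 1.11 (0.83 to 1.23) and the mesoderm median 1.54 (1.04 to 2.24). Endothelial genes were higher in all 16 members, with a median of 4.05 (3.40 relative to the shift), such as tie1 (52.0-fold) and stab2 (60.2-fold), and cartilage and bone genes in 7 of 10, with a median of 2.76 (2.11 relative to the shift), such as spp1 (183 UMIs against 3) and runx2a (9.87-fold). Epidermis genes were lower in 8 of 9 members, with a median of -4.30 (-4.95 relative to the shift).

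Orthologs of EF1-repressed human genes were higher in 20 of 24 members and lower in 1, with a median of 2.29 (1.65 relative to the shift), led by ccn2a (61.8-fold), the fibronectin gene fn1b (26.9-fold), the TGF-beta receptor gene tgfbr2a (16.7-fold) and thbs1a (14.8-fold). The EF1-activated orthologs had 13 of 31 members higher and 6 lower, and a median of 0.65 that lay at the shift of all genes, with il1rapl1a 48.0-fold, steap4 17.6-fold and aurka 10.7-fold higher. FGF-ERK feedback genes were higher in 12 of 16 members and lower in 0, with a median of 1.58 (0.93 relative to the shift): spry4 (15.02-fold) and etv5b (19.8-fold) are targets of FGF signaling. Hedgehog, BMP, Wnt and Notch response genes were higher in 13 of 22 members, with a median of 1.65 (1.00 relative to the shift), led by the Hedgehog-binding gene hhip (19.0-fold). Cell cycle genes were higher in 11 of 19 members, with a median of 1.4 (0.75 relative to the shift), such as the replication genes mcm6 (6.12-fold) and mcm2 (4.90-fold).

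Neural crest lists were mixed in the trunk tumor. The neural crest median was 0.98 (0.34 relative to the shift), with crestin, a marker of zebrafish neural crest, at 207 UMIs against 3 and sox9b 4.44-fold lower, while sox10 had 8 against 14. Schwann and myelin genes had a median of 0.19 that turned to -0.46 relative to the shift, with s100b and mpz higher and the ErbB receptor genes erbb3a and erbb3b 23.5-fold and 17.4-fold lower; pigment genes had a median of 0.28 that turned to -0.37, with oca2 201-fold higher, csf1ra 13.9-fold higher and aox5 25.1-fold lower. The 4 peripheral neuron genes had a median of 0.76 (0.11 relative to the shift), and the 5 central nervous system genes one of 3.41 (2.76), led by gfap (15.3-fold) and snap25b (14.8-fold). Immune genes had a median of 1.33 (0.68 relative to the shift), chromatin regulators 0.89 (0.24) and ETS factors 1.06 (0.41). The immune median turned to -0.38 against the control nuclei outside the epidermis-like clusters, and in the head tumor from 0.69 to -0.24. The medians of apoptosis and p53 genes (0.24) and muscle genes (0.44) turned to -0.41 and -0.21 relative to the shift, and dissociation and stress genes had -0.02 (-0.67). Zebrafish fli1a was 24.0-fold higher (16.4 to 36.6) and fli1b had 38 UMIs against 2, whereas ewsr1a differed by 1.00-fold and ewsr1b was 1.4-fold higher but below the shift.

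The head tumor comes from a mosaic model, another body region and an older fish, and its ratios use the same trunk control. Here tbxta had 1858 UMIs against 0, at least 551-fold higher, lepb had 5808 against 2, and pdgfra was 159-fold higher (117 to 222). Keratin krt5, a structural protein of skin, was 184-fold lower (164 to 207). The transgene had 96 UMIs against 0, at least 28.5-fold higher, which is 12.8 CPM against 345 in the trunk tumor. It is open whether that row matches the construct of the mosaic model, so the levels of the tumors may not be comparable.

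The shift of all 16452 genes was 0.43, with 5882 genes higher and 3020 lower by size (66.1% higher), and 4396 and 4138 after scaling (51.5%); epidermis-like clusters held 2.05% (1.58 to 2.61) of the tumor nuclei. The highest ratios also included lrp1ba (669-fold), nxph1, ecrg4a (308-fold), prx, the vascular growth factor gene angpt2a (1621 UMIs against 2), plcd4a, unc13ba, camk2n1a, htra3a and the matrix metalloproteinase gene mmp9 (192-fold). The lowest included ptgdsb.1 (15 against 11223), krt97, cyp8b2, cyp8b3, fabp1b.2, the MHC class II gene mhc2dab (1 against 1138), apnl, slc51a, entpd8 and adh8a.

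Mesoderm genes were higher in 8 of 11 members and lower in 1, with a median of 3.42 (2.41 to 3.67; 2.99 relative to the shift), above all matched random lists, with ripply1, the presomitic gene msgn1 and mixl1 at 40, 27 and 38 UMIs against 1, 1 and 2. With nuclei thinned to 500 UMIs the median fell to 0.39 over the 4 members left. Posterior hox genes were higher in 5 of 7 members, with a median of 3.45 (3.02 relative to the shift), including hoxa11b (45.6-fold) and hoxa13b (102 UMIs against 0). Fin and limb genes were higher in 13 of 22 members, with a median of 1.27 (0.85 relative to the shift): sall1a was 136-fold and tbx15 58.0-fold higher, and msx2b 124-fold lower. Matrix genes were higher in 20 of 29 members and lower in 1, with a median of 2.33 (2.18 to 2.44; 1.90 relative to the shift), such as prrx1b (65.8-fold), nid2a (47.1-fold) and lamb1a (41.9-fold). Against the control nuclei outside the epidermis-like clusters, again chosen after the data were seen, the mesoderm median was 1.12 (0.58 to 1.31) and the matrix median 0.21 (0.13 to 0.37).

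FGF-ERK feedback genes were higher in 13 of 17 members and lower in 0, with a median of 1.58 (1.15 relative to the shift), and spry4 was 24.9-fold higher. Orthologs of EF1-repressed genes had a median of 1.01 (0.58 relative to the shift), with tgfbr2a 25.9-fold, fn1a 18.6-fold and loxl2b 17.5-fold higher. The EF1-activated orthologs had a median of 0.11 that turned to -0.32 relative to the shift, with tnfaip6 42.8-fold higher and the Notch ligand gene jag1b 15.1-fold lower. Hedgehog, BMP, Wnt and Notch genes had a median of 1.00 (0.58), with notch1a 7.89-fold higher and her9 22.8-fold lower. Endothelial genes were higher in all 12 members, with a median of 3.28 (2.85), and cartilage and bone genes in 8 of 10, with a median of 1.97 (1.54), including runx2a at 20.7-fold. Epidermis genes were lower in all 9 members, with a median of -5.01 (-5.44), and Schwann and myelin genes in 6 of 9, with a median of -3.34 (-3.77), among them nrg1 at 19.7-fold and erbb3b at 25.3-fold. In the adult control nrg1 had 4179 UMIs, against 18 of mbpa and 14 of sox10. The lower list median thus cannot be read as a loss of Schwann cells, and cell makeup enters it.

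Among the other lists in the head tumor, neural crest genes had a median of 0.80 (0.37 relative to the shift), with tfap2b and snai1b 63.1-fold and 21.0-fold higher. Pigment genes had a median of 0.42 that turned to -0.01, with oca2 79.7-fold and ltk 30.0-fold higher. Peripheral neuron genes had a median of -0.81 (-1.23), central nervous system genes 3.50 (3.08) with snap25b 147-fold higher, anterior hox genes 0.71 (0.29), immune genes 0.69 (0.26), cell cycle genes 0.60 (0.17), muscle genes 0.58 (0.15) and ETS factors 1.03 (0.60). The muscle median was negative with thinned nuclei (-0.54) and with members of at least 5 UMIs (-0.81), so its direction is not settled. Dissociation and stress genes had a median of -0.61 (-1.04), apoptosis and p53 genes one of -0.04 (-0.47) and chromatin regulators one of 0.38 that turned to -0.05. The stress genes ier2b and atf3 were 9.85-fold and 5.25-fold lower, fas was 4.38-fold higher, and elf3 was 90.7-fold lower. Zebrafish fli1a was 28.4-fold higher (19.5 to 43.0), sox10 had 17 UMIs against 14, ewsr1a was 1.11-fold higher and ewsr1b 1.34-fold higher, both below the shift.

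**Figure D2:**
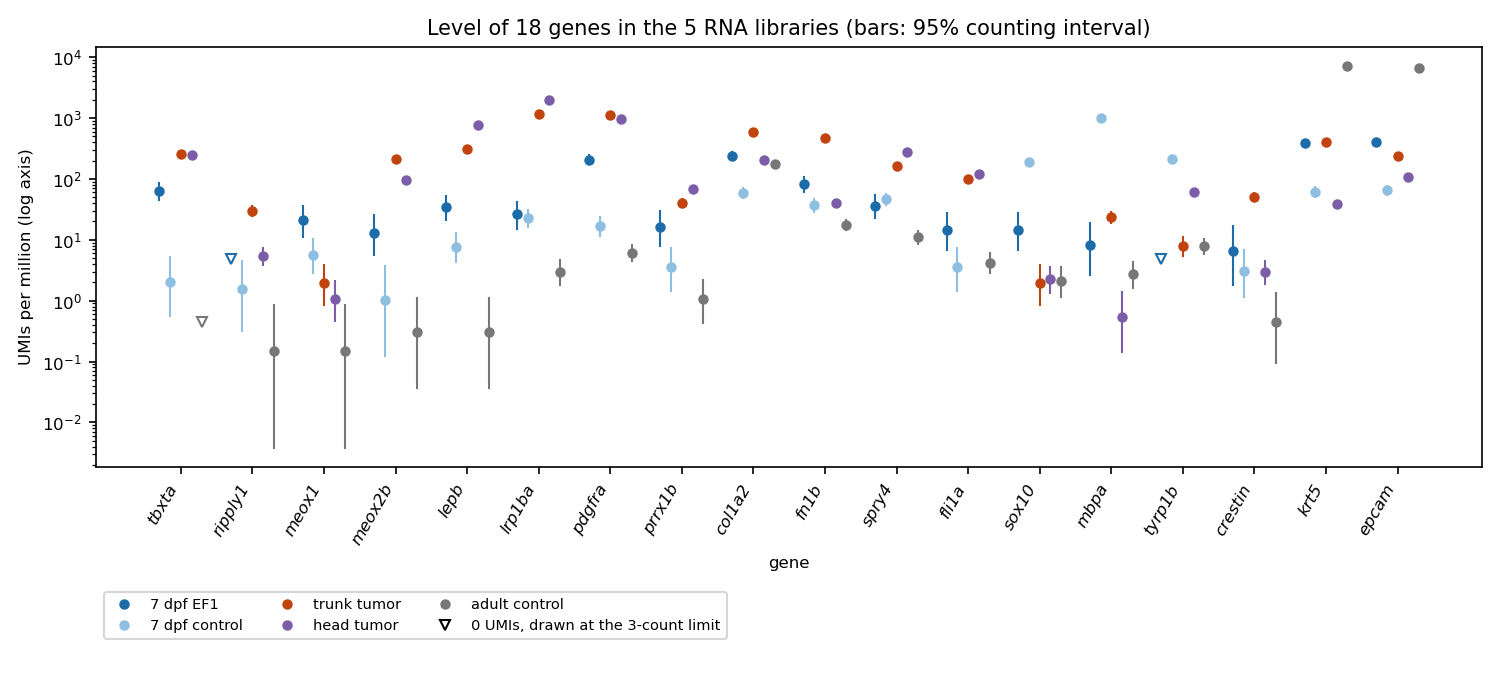
Level of selected genes in CPM (log axis) in the 5 RNA libraries, with 95% counting intervals as bars and open triangles for 0 UMIs drawn at the limit of 3 counts. The gene tbxta reached 63.7 in 7 dpf EF1 nuclei, 259 in the trunk tumor and 249 in the head tumor, against 2.06 in 7 dpf control nuclei and 0 UMIs in adult control. Levels at 7 dpf and in adults are not directly comparable. The 7 dpf totals include mitochondrial ribosomal RNA (27.9% of UMIs in EF1 and 17.7% in control), whose rows had 0 UMIs in the adult libraries.

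The tumors were also compared with each other directly, a comparison added after the data were seen, with a shift of 0.25. Genes higher in the trunk tumor included homer1b (345-fold), pax2b (137-fold), stmn4 (71.1-fold), cntn5 (82.7-fold) and csf1a (137 UMIs against 0). Those higher in the head tumor included tbx20 (271 against 0), tbx1 (25.5-fold), dlgap2a (27.0-fold), asic1b (22.2-fold) and the neuropeptide gene npy (197 UMIs against 1). Anterior hox genes had a median of -1.98 (-2.23 relative to the shift), with hoxa4a and hoxb3a 5.12-fold and 4.34-fold lower in the trunk tumor, while hoxc11a and hoxb13a had 37 and 26 UMIs in the trunk tumor and 0 in the head tumor; the posterior hox list as a whole, with 4 of 11 members higher and 2 lower, had a median of 0.56 (-0.03 to 1.03; 0.32 relative to the shift). Fin and limb genes were lower in the trunk tumor in 8 of 18 members, with a median of -0.81 (-1.06), and endothelial genes higher in 9 of 16, with a median of 1.45 (1.204). Epidermis genes (1.11; 0.87 relative to the shift), dissociation and stress genes (0.76; 0.51), and EF1-activated (0.75; 0.50) and EF1-repressed orthologs (0.76; 0.51) were also higher in the trunk tumor, above nearly all random lists, so cell makeup and stress are not separated from the other differences. Mesoderm genes had a median of 0.26 (0.01 relative to the shift) and matrix genes one of 0.58 (0.33), with crestin 17.5-fold and fn1b 11.8-fold higher in the trunk tumor and tnfaip6 10.6-fold and snap25b 9.93-fold lower.

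Clustering of all 9244 kept nuclei gave 21 clusters, most of them dominated by a single library. Cluster 13 held 240 of the 242 EF1 nuclei and cluster 1 held 1340 of the 1365 control nuclei at 7 dpf, so these clusters cannot be separated from their libraries. Of the sorted control nuclei, 22 (1.61%, 1.01 to 2.43) formed a peripheral neuron-like cluster, a name that was lost at Leiden resolutions of 0.5 and 2 and with at least 1000 UMIs per nucleus. In the trunk tumor, cluster 5 held 36.7% of nuclei, cluster 7 held 22.0%, a fibroblast-like cluster 14.7% (13.2 to 16.4) and an erythroid-like cluster 7.29%, or 3.82% (2.92 to 4.90) of the nuclei with at least 1000 UMIs; in the head tumor, clusters 2, 4 and 6 held 41.2%, 31.9% and 17.4%, and the fibroblast-like cluster 0.192%. The adult control had 4.27% (3.52 to 5.13) fibroblast-like nuclei and 0 nuclei in clusters 4, 5, 6 and 7. The unsorted tissues differed in dissection, so these shares describe the samples taken.

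RNA of tbxta was concentrated in the clusters that the tumors led. A tbxta UMI was found in 30.2% of cluster 5 nuclei (median depth 1855 UMIs) and 43.4% of cluster 7 nuclei (2210) of the trunk tumor, against 2.08% in its epidermis-like cluster 3 (1999) and 3.11% in its fibroblast-like nuclei (1310). In the head tumor the shares were 30.9%, 30.2% and 39.9% in clusters 2, 4 and 6, at median depths of 2226, 2171 and 2140, against 11.5% in epidermis-like cluster 3 (1937.5). In adult control 0 of 2550 nuclei had one. Within the trunk tumor, clusters 5 and 7 together had the mesoderm list higher in all 5 measured members than the fibroblast-like nuclei, with a median of 2.90 (2.53 relative to the shift), and tbxta 14.6-fold (7.92 to 30.6) and meox2b 5.05-fold higher. Cell cycle genes were higher there in 9 of 15 members, with a median of 1.22 (0.85), and dissociation and stress genes lower in 13 of 22, with a median of -1.46 (-1.83). Clusters 5 and 7 also differed from each other, with crestin in 5.41% and 22.0% of nuclei and lepb in 31.6% and 6.50%. These clusters were drawn from the same RNA, so differences between them are not independent of the clustering.

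Transgene RNA, which took no part in the clustering, was spread more widely in the trunk tumor. It was found in 39.4% of cluster 5 nuclei, 49.4% of cluster 7 nuclei, 38.8% of fibroblast-like nuclei and 66.7% of epidermis-like cluster 3 nuclei, against 0 of 2550 control nuclei at a median depth of 2267 UMIs.

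**Figure D3:**
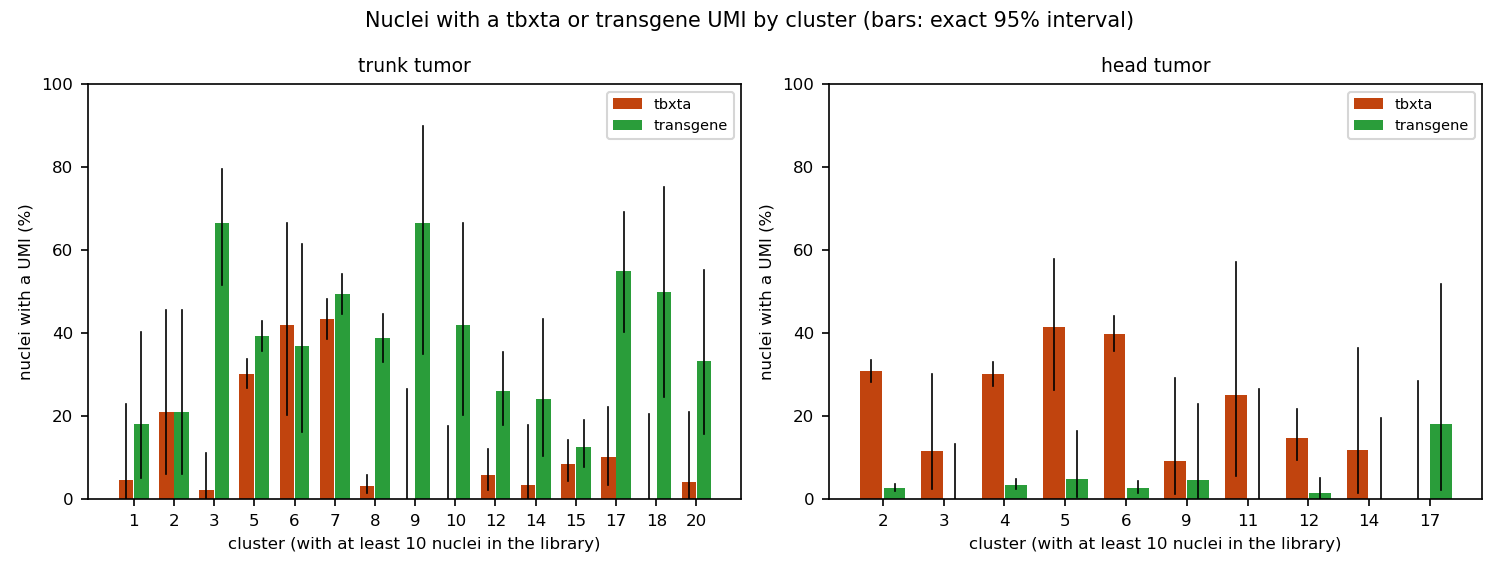
Percent of nuclei with a tbxta or a transgene UMI in each cluster with at least 10 nuclei of the trunk tumor and of the head tumor, with exact 95% intervals as lines. In the trunk tumor tbxta was found in 30.2% of cluster 5 and 43.4% of cluster 7 nuclei, while the transgene reached 66.7% in cluster 3, which is epidermis-like.

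The question whether genes higher at 7 dpf were also higher in tumors was put to the 50 genes with the highest 7 dpf ranking. Of these, 17 were acinar and 9 were muscle genes, and 7 were measured in the trunk tumor, with a median of -1.41 (-2.65 to -0.20; -2.06 relative to the shift), and 8 in the head tumor, with a median of -1.93 (-2.55 to -1.11; -2.36). Without acinar and muscle genes, a choice made after seeing the set, the medians were -1.14 and -1.65. Of the first 50 genes, 0 were on the epidermis list, but skin transcripts were higher at 7 dpf and most adult control nuclei were epidermis-like. Cell makeup can thus enter these medians, which do not show that genes raised by EF1 fall in tumors. In the reverse direction, also added later, the 50 genes highest in the trunk tumor had a median of -0.90 at 7 dpf, with 9 of 28 measured members higher and 13 lower, and those of the head tumor one of -0.89; relative to the shift both turned positive, at 0.30 and 0.31.

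Chromatin accessibility was compared through the deposited peak lists (positions on GRCz11). The EF1 multiome library had 47374 peaks and the 7 dpf control 72028, and 68.3% of the EF1 peaks overlapped a control peak while 88.8% overlapped a peak of the separate EF1 chromatin library. Of the control peaks, 87.2% also overlapped a peak of that separate library, so the 88.8% is not particular to EF1 peaks. In both EF1 libraries and not in the control were 10118 peaks, of which 71.7% (70.9 to 72.6) overlapped a trunk tumor peak, 72.1% (71.3 to 73.0) a head tumor peak and 49.4% (48.5 to 50.4) an adult control peak. For the 8797 control-only peaks these shares were 23.6%, 26.7% and 20.01%, and for the 31938 shared peaks 93.6%, 93.3% and 83.8%. These sets depend on both EF1 libraries being used, as settings chosen after the data were seen show. Without the separate EF1 library there were 15012 EF1-only peaks, with shares of 59.8%, 59.95% and 41.2%. The 39645 control-only peaks then had shares of 54.6%, 57.8% and 42.9%. The sets thus lay much closer, with EF1-only peaks still somewhat higher in the tumors and lower in adult control. Without the EF1 multiome library there were 83606 EF1-only and 9222 control-only peaks. Their shares were 44.0%, 48.5% and 30.1% against 25.1%, 27.9% and 21.1%. Among the 20000 peaks with the most cut sites per library, the EF1-only shares were 45.2%, 46.0% and 18.4%. The control-only shares were then 17.0%, 11.3% and 10.9%, and those of shared peaks 90.5%, 84.5% and 73.6%. Peaks were called per library, and they covered 110 Mb in the trunk tumor, 120 Mb in the head tumor and 93.5 Mb in the adult control, so covered length can raise a share. The shares did not always follow it, since shared peaks overlapped the trunk tumor slightly more often than the head tumor. With 20000 peaks in each library the EF1-only gap to adult control remained, so the number of peaks alone does not give that gap.

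Single regions showed both patterns. The EF1-only peak with the most cut sites, 175, lay on chromosome 9 at 25365795 to 25366494 and was also a peak in both tumors and in adult control; the next, with 124, lay on chromosome 13 at 19168293 to 19169162 and was a peak in both tumors but not in adult control. By cluster, EF1-only peaks took 5.24% of cut sites in trunk tumor cluster 5 and 4.72% in cluster 7. The trunk tumor's fibroblast-like nuclei had 4.73%, and its epidermis-like clusters 3, 9 and 10 had 5.38%, 5.78% and 5.56%. In the head tumor they took 5.88%, 5.60% and 5.57% in clusters 2, 4 and 6, against 5.75%, 5.94% and 4.82% in epidermis-like clusters 3, 9 and 11. Cut sites were counted in each library's own peaks, so these shares compare only within a library.

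**Figure D4:**
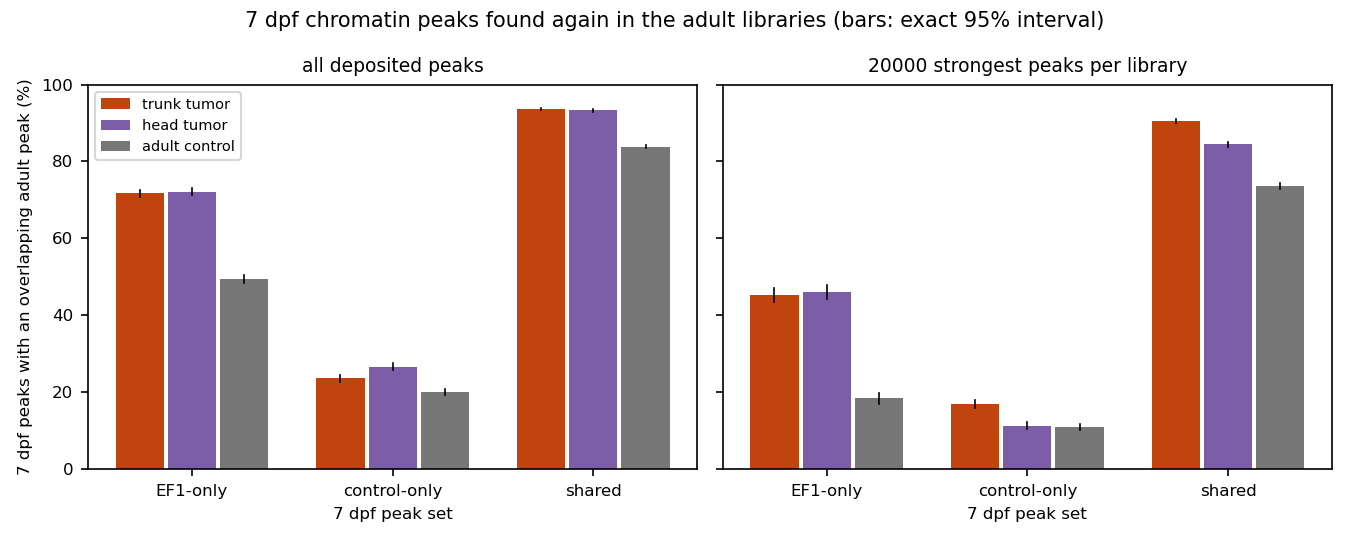
Percent of 7 dpf peaks that overlap a peak of the trunk tumor, head tumor or adult control, for EF1-only, control-only and shared 7 dpf peaks, with exact 95% intervals as lines. For EF1-only peaks the adult control bar stands at 49.4% with all peaks and 18.4% with the 20000 strongest, below both tumors in each panel. It is also the lowest bar for control-only and shared peaks.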

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

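All tests in this part were chosen after the main results were seen. Only for matrix genes against control nuclei outside the epidermis-like clusters was the expected outcome written down before that test's own result was seen.

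Some gene lists moved in opposite directions at 7 dpf and in the tumors, with the list median on one side of 0 in each. For cartilage and bone genes the median log2 ratio was -2.27 at 7 dpf (4 genes) and 2.76 in the trunk tumor (10 genes), a difference of -5.03, and 1.97 in the head tumor, a difference of -4.24. For epidermis genes the values were 2.65, -4.30 and -5.01, with differences of 6.95 and 7.66. For central nervous system genes they were -2.80, 3.41 and 3.50, with differences of -6.20 and -6.30. The control differs too, sorted at 7 dpf and unsorted in adults, and the differences themselves were not tested. In the separate EF1 chromatin library, which has no control library of its kind, 194 fragments (168 to 223) lay on EGFP, 141 on DSRED and 36 on CRE sequence among 24334987 fragments, above the 3 that a count of 0 allows; NTR, another added sequence, had 1. Fish with these constructs are expected to give such fragments, so they show presence only.

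Pancreatic, muscle and matrix RNA in the sorted EF1 nuclei at 7 dpf is the first pattern weighed, since the GFP gate should leave such cells out. Acinar RNA was present in 100% of the EF1 nuclei and took at most 6.55% of any nucleus's UMIs, which argues against acinar nuclei and is what free RNA from other cells would give. Its 10 richest nuclei hold 7.08% of its UMIs, against at most 4.55% in redraws by depth, so free RNA would have to differ in amount between nuclei. Muscle RNA splits after inspection of the nuclei: 10 nuclei hold 58.8% of its UMIs, against at most 5.92% in redraws and beyond the 2 times that bound set for this test, while 96.6% of the other 232 nuclei have a muscle UMI, as free RNA would give. Matrix RNA varied over nuclei beyond counting by 67.1% (54.8 to 79.3) against 23.7% (20.7 to 27.3) for acinar RNA, which argues against a single pool of free RNA shared with acinar transcripts. This is not particular to matrix RNA, since epidermis RNA (49.2%, 37.9 to 57.7) also lies above acinar RNA. A first measure, variance over mean, pointed the other way (6.72 against 10.2), but it grows with the number of UMIs (1747 against 22451) and was replaced after both values were seen. Whether matrix RNA belongs to EF1 cells or to other nuclei in the sort stays open, as do tbxta, with 39 UMIs and a variance over mean of 1.05, and any biological cause.

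Transgene RNA outside clusters 5 and 7 of the trunk tumor is the second pattern. Between clusters the transgene UMIs per nucleus differed by up to 19.6-fold (11.98 to 32.5), or 15.7-fold in CPM (9.63 to 26.1). The highest was epidermis-like cluster 9, with 12 nuclei, and the lowest erythroid-like cluster 15. A single pool of free RNA alone would not give this range. The range cannot exclude free RNA as the source in the lower clusters. Counting of ordinary zebrafish reads as transgene is limited to 0.451 CPM by the adult control, against 137 in the lowest trunk tumor cluster. This limit holds for genes that the control expresses, and fli1a stood at 4.21 CPM there against 101 in the trunk tumor. The head tumor, with fli1a at 120 CPM, had 12.8 CPM in the transgene row. Doublets with nuclei of clusters 5 and 7 would bring tbxta along. Transgene UMIs per tbxta UMI were 160-fold (28.1 to 6366) those of clusters 5 and 7 in epidermis-like nuclei (145 transgene and 1 tbxta UMIs) and 19.8-fold (10.4 to 42.3) in fibroblast-like nuclei, which argues against such doublets there, although tbxta took part in the clustering. The transgene level in epidermis-like cluster 3, 629 CPM (489 to 796), also exceeded the 285 and 364 of clusters 5 and 7. In the other clusters the value was 2.29 (1.74 to 3.05), around the bound of 2, so doublets cannot be told apart there. Transcription of the transgene in other lineages of the tumor tissue may explain the rest and was not tested.

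A lower share of epidermis in the tumors is the third pattern, as it would raise the lists of every other cell type. Against control nuclei outside the epidermis-like clusters, the mesoderm median in the trunk tumor was still 1.54 (1.04 to 2.24; 1.17 relative to the shift), which the lower share alone does not give, although 5 of its 9 members had 0 control UMIs and entered at their bound. The matrix median in the trunk tumor was 1.11 (0.83 to 1.23), within counting error of the bound of 1 set for this test. That bound was a choice, so this test cannot separate the lower share from a higher level there. The interval lay above 0, but it covers counting error only, and the remaining nuclei also differ in makeup. The mesoderm median in the head tumor was 1.12 (0.58 to 1.31), also within counting error of that bound, but this test cannot decide there. Members with 0 control UMIs enter at the floor, whose CPM rises when control nuclei are removed. The mesoderm medians of both tumors can thus fall in part through the floor, and how much was not tested. For tbxta, with 1858 head tumor UMIs, the count was 0 over all 2550 adult control nuclei, epidermis-like or not. The matrix median in the head tumor fell from 2.33 to 0.21 (0.13 to 0.37), under the bound of 1, as a lower share of epidermis would give. How much of the 2.33 is due to that share is not settled. Removing the epidermis-like nuclei raises the control level of any gene expressed mainly in other nuclei, and the control nuclei left include 109 fibroblast-like ones. The intervals were added after the medians were seen, and tumor age, region and model stay open as biological differences for the head tumor.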

How the results depend on the processing

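The doublet scores, mitochondrial, epidermis-like and leave-one-out settings below were chosen after the results were seen; the other settings were planned. No paired analysis was possible because no sample shares an animal with a sample of its comparison group in the labels. The searches for GGAA repeats and for motifs and the genes near repeat peaks, with their alternatives, were not run because genome sequence was not used here. Over planned settings, list medians gave 424 values, of which 289 stayed within their counting interval, 123 moved beyond it and 12 reversed; named genes gave 1768, with 1456, 306 and 6; shares of nuclei 45, with 37, 8 and 0; the derived set 4, all within; and peaks 16, with 4, 12 and 0. Over added settings, lists gave 190 values, with 150, 36 and 4, named genes 714, all within, and peaks 16, with 2, 14 and 0. Reversed means a change of sign in a value whose counting interval excludes 0; medians with 0 in their interval can change sign without being counted. Unless the construction shows it, the cause was not tested.

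Median of ratios scaling, which subtracts the shift of all genes, reversed at 7 dpf FGF-ERK feedback (0.23), apoptosis and p53 (1.03), ETS factors (0.0399) and socs3a (0.14); in the trunk tumor EF1-activated orthologs (-0.000744), muscle (-0.21) and ewsr1b (-0.16); and in the head tumor pigment cells (-0.0123), chromatin regulators (-0.0516) and ewsr1b (-0.00721). It moved Schwann and myelin (-2.50), mesoderm (3.10) and matrix (2.36) at 7 dpf and matrix in the trunk (2.21) and head tumor (1.90). Thinning to 500 UMIs per nucleus reversed foxo1b at 7 dpf (0.17), muscle in the trunk (-0.80) and head tumor (-0.54), and pax7b (-0.0620) and mcm4 (-0.18) in the head tumor. It moved Schwann and myelin at 7 dpf to -2.15, mesoderm to 2.47 in the trunk and 0.39 in the head tumor, where 6 and 4 members were left, and matrix to 2.29 and 1.46; no mesoderm gene was left at 7 dpf. With all deposited nuclei, muscle reversed in the trunk (-0.12) and head tumor (-0.00566), and Schwann and myelin at 7 dpf moved to -4.91. With members of at least 5 UMIs, muscle in the head tumor reversed (-0.81) and mesoderm there moved to 2.40 over 16 members. With at least 1000 UMIs per nucleus, mesoderm at 7 dpf moved to 3.73 over 2 members, and the adult control had 83.6% epidermis-like and 3.40% fibroblast-like nuclei; at Leiden resolution 2 the epidermis-like share was 70.4%. The derived set of 25 genes had no measured member in either tumor.

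Leaving out mitochondrial transcripts reversed apoptosis and p53 at 7 dpf (0.0736). Control without epidermis-like clusters reversed immune cells in the trunk (-0.38) and head tumor (-0.24) and pigment cells in the head tumor (-0.71), and moved mesoderm to 1.54 and 1.12 and matrix to 1.11 and 0.21. With overlap of at least 50% of the smaller peak, EF1-only peaks overlapped the head tumor in 71.0% and the adult control in 48.2%. With the 20000 peaks with the most cut sites there were 2925 EF1-only peaks, with shares of 45.2%, 46.0% and 18.4% in the trunk tumor, head tumor and adult control. Leaving out an EF1 chromatin library gave 15012 to 83606 EF1-only peaks, with shares of 44.0% to 59.8%, 48.5% to 59.95% and 30.1% to 41.2%; fewer libraries must then hold a peak. In all these peak settings the tumors stayed above the adult control. The same held for control-only and shared peaks, so this order is not particular to EF1-only peaks. Depth is one limit of the 7 dpf comparison: with 242 EF1 nuclei, 4.90 CPM is the level that a count of 0 allows. Over both 7 dpf libraries 3 mesoderm genes were measured, and 5 with all deposited nuclei.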

Other observations

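The comparisons in this part were all chosen after the data were seen. In epidermis-like nuclei, matrix genes were higher than in the adult control in the trunk tumor in 8 of 14 members and in the head tumor in 13 of 15, with medians of 2.08 (1.95 relative to the shift) and 2.74 (2.18). Free RNA from the most common nuclei of each tissue would give values of this kind too, which was not tested here.

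The tumor-led clusters were also set against the fibroblast-like nuclei of the adult control. EF1-activated orthologs were lower in 11 of 21 members in trunk tumor clusters 5 and 7, with a median of -1.22 (-1.48 relative to the shift), and in 12 of 22 in head tumor clusters 2, 4 and 6, with a median of -1.40 (-1.24). In the head tumor clusters lepb had 5625 UMIs against 0 and camk2n1a 5694 against 0, and ETS factors were higher in 7 of 13 members, with a median of 1.39 (1.55). Matrix genes helped to name the fibroblast-like cluster, so ratios to it are not given for the matrix list or for EF1-repressed orthologs, which hold some of these genes.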
